A study of Homo sapiens with 4 samples.

How the data were processed

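The material was RNA from HaCaT cells, a spontaneously immortalised human keratinocyte line that is an established model of epidermal cells. Per the labels' protocols, the line was transduced with lentivirus to give a stable line that overexpresses TCN1 and a negative control line, and polyA RNA was taken for sequencing. TCN1 encodes transcobalamin 1, also called haptocorrin, a secreted protein that binds vitamin B12 (cobalamin). The 4 libraries comprised 2 of the negative control (NC) and 2 of the TCN1 overexpression line (TCN1_OE), and groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

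Per the labels' protocols, the libraries were made with the NEBNext Ultra RNA kit, which does not mark strand, and were sequenced on an Illumina NovaSeq X Plus. Per the submitters' processing notes, reads were aligned with HISAT2 and counted per gene with HTSeq 0.13.5, on the human build GRCh38. The HISAT2 version, the annotation release and the strand and multi-mapping settings are not given in the sources used here. The deposited files hold, per the file headers, a raw count and an FPKM value (fragments per kilobase of gene length, scaled to the library total) for each of 29209 genes in each library. The deposited FPKM was made from the deposited count: dividing count by FPKM and by the library's summed counts gave a whole number of base pairs of gene length in 100% of the values above 0, within a tolerance of 1e-04 bp. All rows name a gene, and the library totals below are the sums of the listed counts, so the number of reads sequenced is unknown.

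The libraries held 19973550 and 11593377 counts in NC and 16586500 and 14756073 counts in TCN1_OE, with at least 1 count for 24610, 22186, 24711 and 23343 genes. At a gene length of 1500 bp, 3 counts correspond to between 0.100 and 0.173 FPKM, which sets the level below which a gene cannot be told from absence. Reads without molecular identifiers are not independent molecules, so such floors cover counting error only. The chi-square per degree of freedom was 8.40 between the 2 NC libraries and 8.54 between the 2 TCN1_OE libraries, above counting noise, which library preparation alone can give, so it does not show separate cultures. Each library was counted as a replicate, as its title numbers it.

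Differential expression was tested on the deposited counts with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, robust estimation, group as the only term and all 4 libraries in the fit. The plan had been written for FPKM alone, with limma, and named this count test as its replacement should the files hold whole counts. Genes were kept by filterByExpr with its minimum count of 10, which left 15113 genes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A gene past this threshold is called higher or lower. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. With 2 libraries against 2 an exact two-sided permutation test cannot go below 0.333, so all tests rest on a spread shared across genes.

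Before the data were examined, 35 gene lists with 969 genes were fixed: pathways and cell states that fit keratinocytes and vitamin B12, and markers of other skin cell types. Of these genes, 48 were not among the listed genes. Lists were tested with camera (limma 3.58.1) on log2(FPKM + 0.5) of the 11470 genes with a mean of at least 1 FPKM, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 31 lists with at least 5 such genes. TCN1 itself was left out of its list. Members were counted as higher or lower among the genes tested by edgeR, with the adjustment over all genes tested and with that over the list alone. Camera was repeated with an estimated correlation, and fry (limma) was run as well.

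The genes named were chosen by a rule fixed before the data were examined. TCN1 came first. The 12 largest log2 fold changes in each direction followed, among genes with an adjusted p under 0.05, a mean of at least 5 FPKM in the higher group, groups that did not overlap and a proper symbol. For each list described, up to 4 members with the smallest adjusted p were named, except 3 members that are not reported here. Genes named outside this rule are said to be so.

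The edgeR and camera steps were tested on simulated counts for the same 15113 genes, with the real library sizes and 200 genes changed. For the comparison of 2 TCN1_OE with 2 NC libraries, edgeR recovered 46 of 67 genes changed by 1.5-fold, 64 of 67 changed by 2-fold and 66 of 66 changed by 4-fold, with 8 false calls. Limma on log2 FPKM recovered 14, 52 and 63 of the same genes. A shift of -0.4 on the log2 scale given to the G1/S list was called, and no other list was. Each gene was drawn independently, with the spread that edgeR had fitted as a trend with expression level, not with a spread of its own. False list calls that come from correlation between genes could therefore not arise in this simulation.

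Gene coordinates, overlaps between exons of different genes on either strand, GC content and neighbouring genes came from GENCODE release 29 on GRCh38, matched by Ensembl identifier for 27118 of the 29209 listed genes. Without strand, reads from overlapping genes cannot be told apart, and 9 of the 75 called genes had more than 10% of their exonic bases under another gene. Genes with near-identical copies or pseudogenes, among them HSPA8, KRT81, the histone, HLA, SERPINB3 and SERPINB4, and mitochondrially encoded genes, are uncertain to the extent that the authors' counting split or dropped shared reads.

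The alternatives tried were other pseudocounts, filters on low values and scalings, limma on log2 FPKM, DESeq2 1.42.0, a fit with the replicate number as a block, leaving out each library in turn, removal of mitochondrially encoded genes, a 2-fold minimum, an estimated correlation and fry. Fits without robust estimation, with median-of-ratios factors, on counts thinned to the smallest library and with camera on log2 CPM were added after seeing the data.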

Results

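The transcriptome of HaCaT keratinocytes carrying a lentiviral TCN1 construct (TCN1_OE, 2 libraries) was compared with that of negative control cells (NC, 2 libraries), to find which genes differ in expression when TCN1 is overexpressed. The measure was polyA RNA-seq, given as counts and FPKM per gene. Library totals were 19973550 and 11593377 counts in NC and 16586500 and 14756073 counts in TCN1_OE. The first principal component of log2 CPM, with 43.5% of the variance, placed both TCN1_OE libraries on one side of 0 and both NC libraries on the other. The second, with 33.2%, separated replicate 1 of both groups from replicate 2 in the same way. The highest Pearson correlation between libraries was across groups, 0.9843 for NC replicate 1 with TCN1_OE replicate 1. It was 0.9828 within NC, 0.9837 within TCN1_OE and 0.9765 to 0.9780 for the other pairs across groups. The chi-square per degree of freedom was lower within groups, 8.40 and 8.54, than across them, 10.4 to 19.9. Values are given below as mean ± SD over the 2 libraries of a group, and log2 fold changes as TCN1_OE over NC ± SE.

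TCN1 was 44.5-fold higher in the TCN1_OE libraries. The gene (ENSG00000134827), which encodes a secreted vitamin B12-binding protein, lies on chromosome 11 at 59852800 to 59866575 of GRCh38, on the minus strand, and none of its exonic bases is under another annotated gene. Its counts were 50 and 17 in NC and 1700 and 1253 in TCN1_OE, or 1.32 ± 0.49 against 62.5 ± 8.29 FPKM. The log2 fold change was 5.48 ± 0.20, with an edgeR adjusted p of 2.4e-06. The labels do not say which part of the transcript the vector carries, so these counts may hold vector and endogenous transcript together. Under all alternatives run the log2 fold change lay between 4.78 and 5.98 and the gene stayed called.

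Among 15113 genes tested with edgeR, 43 were higher and 32 lower in TCN1_OE at an adjusted p under 0.05. The suprabasal keratins KRT10 and KRT1 were among those that rose, and the replication factor CDC6, the one-carbon enzyme MTHFD1L and the chaperone HSPA8 were among those that fell. Over the 74 called genes besides TCN1 the median size was 0.73 on the log2 scale, and 15 of them rose and 5 fell by at least 2-fold. The largest of these changes, named outside the rule, were at low expression: DHRS4 and NOMO1 stood at -5.01 and -3.54, PIP4P1 and MOB2 at 4.41 and 3.92, and DHRS4 stood at -3.97 without NC replicate 1, where it was not called (edgeR adjusted p 0.164). At an unadjusted p under 0.05 there were 907 higher and 1029 lower genes, where 756 in all were to be had by chance. The number called depended on the test: limma on log2(FPKM + 0.5) called 1 gene higher, which was TCN1, and 0 lower, and DESeq2 called 95 higher and 109 lower. Leaving out 1 library raised the counts, to 114 higher and 142 lower without NC replicate 1, 128 and 106 without NC replicate 2, 188 and 117 without TCN1_OE replicate 1, and 104 and 117 without TCN1_OE replicate 2.

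**Figure D1:**
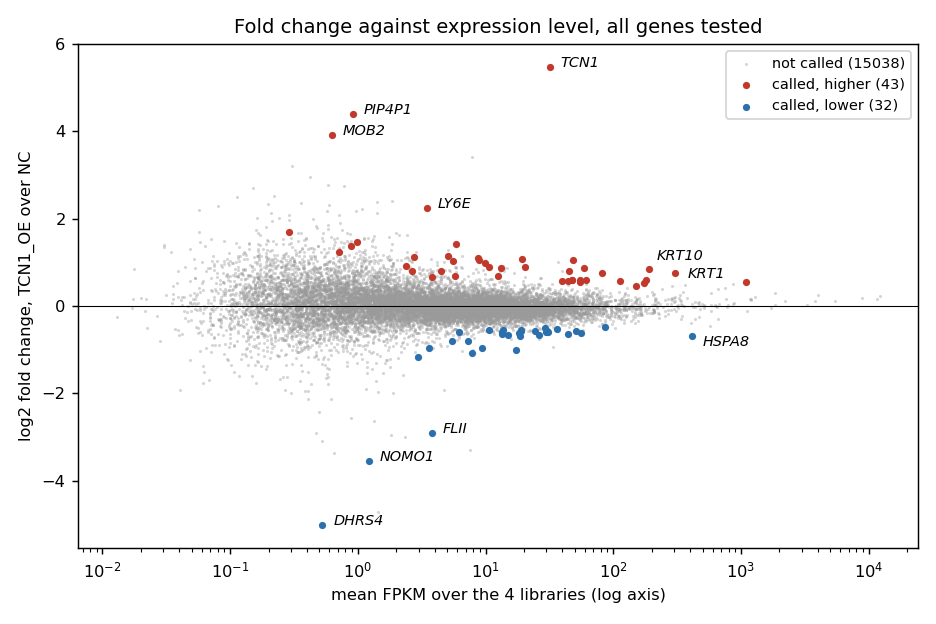
Log2 fold change of TCN1_OE over NC (vertical axis) against the mean FPKM of the 4 libraries (horizontal log axis) for each of the 15113 genes tested; 43 genes called higher by edgeR are red, 32 called lower are blue and 15038 not called are grey. TCN1 stands at 5.48, KRT10 and KRT1 lie at 0.84 and 0.77, and the other called genes with folds above 4 have means of a few FPKM or less.

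Among called genes with a mean of at least 5 FPKM in TCN1_OE, the 12 largest rises besides TCN1 were as follows. LY6E (ENSG00000160932, chromosome 8, 143017982 to 143023832), a GPI-anchored surface protein, rose from 1.22 ± 0.12 to 5.74 ± 1.14 FPKM, with a log2 fold change of 2.24 ± 0.23 and an edgeR adjusted p of 0.0053. PLA2G2A (chromosome 1, 19975431 to 19980416), a secreted phospholipase A2, rose from 3.11 ± 0.89 to 8.54 ± 1.92 FPKM, by 1.43 ± 0.25 on the log2 scale. CASP14, a caspase of the cornifying epidermis, rose by 1.15 ± 0.17, from 3.13 ± 0.48 to 7.04 ± 0.33 FPKM. PIK3IP1, an inhibitor of PI3 kinase, rose by 1.10 ± 0.12, and TP53INP1, a p53-inducible stress protein, by 1.05 ± 0.12. BMF, a pro-apoptotic BH3-only protein, rose by 1.04 ± 0.13, from 3.60 ± 0.34 to 7.44 ± 0.20 FPKM. GPR15LG, the secreted ligand of the chemoattractant receptor GPR15, rose from 31.4 ± 2.51 to 65.7 ± 4.48 FPKM. The noncoding RNA LINC02518 rose by 1.09 ± 0.17. CCDC80, a secreted matrix protein, doubled from 6.66 ± 0.03 to 13.3 ± 0.45 FPKM, a log2 fold change of 1.00 ± 0.09. The histone gene H2BC21, the secreted glycoprotein OLFM4 and the tight junction protein CLDN8 rose by 0.89 ± 0.13, 0.89 ± 0.11 and 0.88 ± 0.14. The edgeR adjusted p of these 12 genes lay between 0.0032 for CCDC80 and 0.0475 for PLA2G2A.

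The 12 largest falls were taken in the same way, among called genes with a mean of at least 5 FPKM in NC. FLII (ENSG00000177731, chromosome 17, 18244836 to 18258916), a gelsolin-family actin-remodelling protein, fell from 6.71 ± 1.94 to 0.892 ± 0.288 FPKM, with counts of 673 and 591 against 72 and 102. Its log2 fold change was -2.91 ± 0.26, with an edgeR adjusted p of 0.0032. SSBP1 (chromosome 7, 141738321 to 141787922), which binds single-stranded mitochondrial DNA, had a log2 fold change of -1.08 ± 0.19, from 10.7 ± 3.36 to 5.09 ± 0.50 FPKM. KRT81, a hair keratin with close paralogs, had a log2 fold change of -0.999 ± 0.137, and the activin antagonist FST fell from 12.5 ± 0.30 to 6.39 ± 0.09 FPKM. MTHFD1L, the mitochondrial formate-producing enzyme of one-carbon metabolism, had a log2 fold change of -0.81 ± 0.11, from 9.20 ± 0.11 to 5.26 ± 0.05 FPKM. The ribosome assembly genes URB2 and WDR43 stood at -0.80 ± 0.13 and -0.66 ± 0.12. HSPA8, the constitutive HSP70 chaperone, fell from 508.1 ± 16.4 to 319.5 ± 11.2 FPKM, a log2 fold change of -0.67 ± 0.08. The matrix protein gene THBS1 fell from 31.9 ± 0.56 to 20.1 ± 0.11 FPKM, and F3, which encodes tissue factor, stood at -0.63 ± 0.11. ODC1, the rate-limiting enzyme of polyamine synthesis, stood at -0.64 ± 0.11 and the neurofilament gene NEFL at -0.69 ± 0.10, with 11.3% of the exonic bases of NEFL under another gene. The edgeR adjusted p of these 12 genes lay between 0.0032 for FLII and 0.04996 for WDR43. With edgeR restricted to genes of at least 1 FPKM, PLA2G2A, SSBP1, WDR43, ODC1 and F3 were no longer called, nor were FN1 and TNFSF10, described below.

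**Figure D2:**
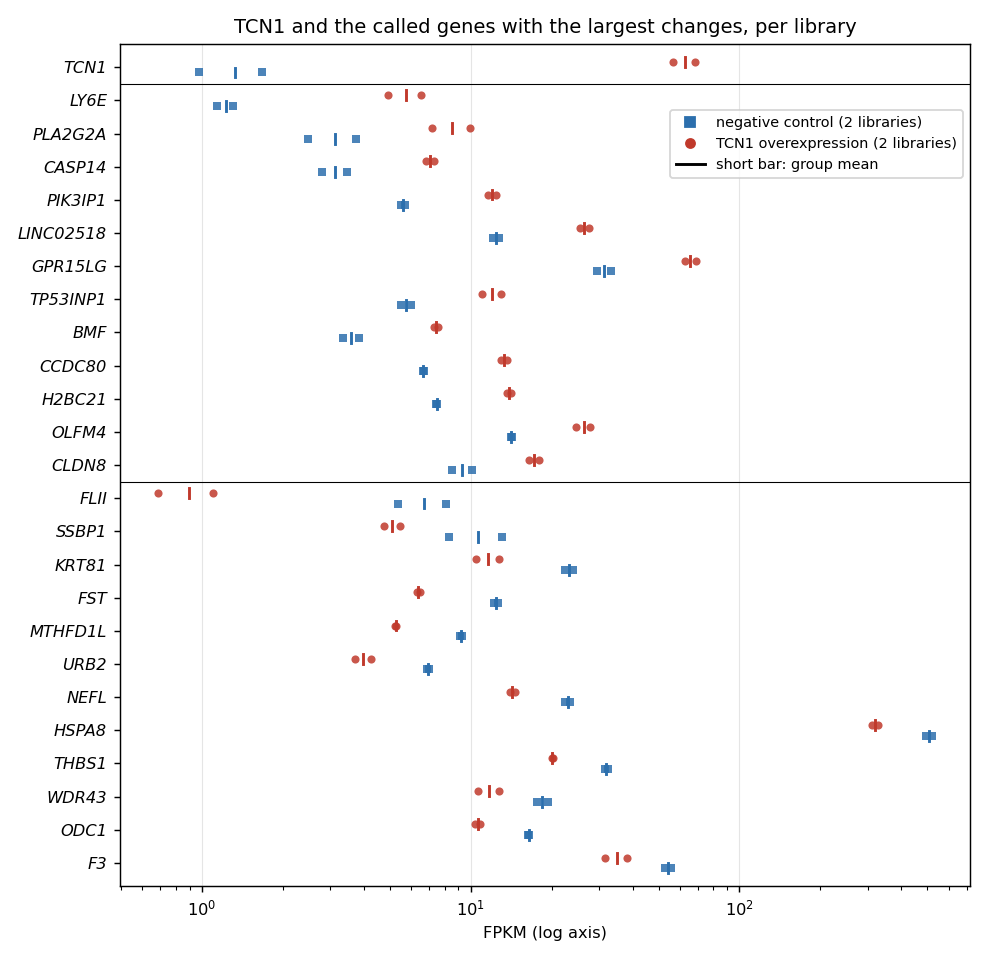
FPKM on a log axis for TCN1 and the 12 genes with the largest rise and the 12 with the largest fall, from the top down; squares are the 2 NC libraries, circles the 2 TCN1_OE libraries and short bars the group means. The libraries of the 2 groups are apart for each of the genes, from 1.32 against 62.5 FPKM for TCN1 to 6.71 against 0.892 FPKM for FLII.

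Of the 31 fixed gene lists that could be tested, 13 passed camera, 7 of them higher and 6 lower in TCN1_OE, while 0 passed with an estimated correlation and 3 with fry (limma). Over the 13 lists the estimated correlation ran from -0.098 (antigen presentation) to 0.323 (G2/M and mitosis). In the G1/S list it was 0.0066, under the preset 0.01, so a higher correlation between genes does not account for the loss of that call. All 42 tested members of the G1/S and DNA replication list had a negative log2 fold change, with a median of -0.37 and a camera (limma) adjusted p of 6.2e-19, or 0.320 with an estimated correlation; 1 member fell adjusted over all genes, and 33 fell adjusted over the list alone. The 1 was CDC6, which loads the replicative helicase, at -0.57 ± 0.09, from 36.3 ± 0.86 to 24.5 ± 0.46 FPKM. The next members did not pass over all genes: the repair exonuclease EXO1 stood at -0.60 ± 0.11, and the helicase factors MCM10 and MCM6 at -0.64 ± 0.12 and -0.45 ± 0.09. Of 47 tested G2/M and mitosis genes, 43 had a negative value, with a median of -0.18 and a camera adjusted p of 5.9e-06, or 0.445 with an estimated correlation, but 0 passed edgeR over all genes or over the list alone. The mitotic activator CDC20 stood at -0.33 ± 0.09, the survivin gene BIRC5 at -0.33 ± 0.09, the transcription factor FOXM1 at -0.35 ± 0.10 and cyclin CCNA2 at -0.29 ± 0.09.

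The replication-dependent histone list went the other way. Of 19 tested histone genes, 15 had a positive value, with a median of 0.34 and a camera adjusted p of 1.3e-05, or 0.395 with an estimated correlation. None passed edgeR over all genes and 1, H2BC5 at 0.64 ± 0.14, passed adjusted over the list alone. H2AC8, H4C8 and H3C10 stood at 1.01 ± 0.37, 0.54 ± 0.21 and 0.47 ± 0.19. Without a filter on low values the list was not called, with an adjusted p of 0.0874. Transcripts of these genes mostly lack a polyA tail, so their level in a polyA library can also depend on the selection. The mitochondrially encoded list, which depends on RNA quality as well, was higher too, with a camera adjusted p of 0.0035 and 11 of 12 tested members positive. With an estimated correlation its adjusted p was 0.428. Its median was 0.17, no member passed edgeR over all genes or over the list alone, and MT-ATP6, MT-CO3, MT-CO2 and MT-ND1 stood at 0.24 ± 0.09, 0.18 ± 0.08, 0.23 ± 0.10 and 0.17 ± 0.08. These genes took 5.23 ± 0.14% of the counts in NC and 5.84 ± 0.27% in TCN1_OE, a difference in the same direction as the split of the groups described here. The mitochondrial list was not called after quantile normalisation, with an adjusted p of 0.779, nor without NC replicate 2, with 0.169.

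Genes of folate, one-carbon and serine metabolism, the pathway that shares methionine synthase with vitamin B12, lay lower. Of 23 tested members, 3 fell over all genes and 10 adjusted over the list alone, with a median of -0.26 and a camera adjusted p of 8.2e-06, or 0.357 with an estimated correlation. Besides MTHFD1L, the purine synthesis enzyme PAICS fell from 29.2 ± 1.21 to 19.6 ± 1.04 FPKM and the serine synthesis enzyme PSAT1 from 67.9 ± 4.13 to 44.7 ± 3.96 FPKM, with log2 fold changes of -0.58 ± 0.09 and -0.61 ± 0.10. MAT2A, which makes S-adenosylmethionine, stood at -0.41 ± 0.08 without passing, with 12.4% of its exonic bases under another gene. The cobalamin handling list itself did not pass, with a camera adjusted p of 0.838 over 12 genes besides TCN1. Its members with the smallest adjusted p were the transcobalamin receptor CD320, at 9.71 ± 1.21 FPKM in NC and 6.26 ± 0.73 FPKM in TCN1_OE, the methionine synthase reductase MTRR at -0.32 ± 0.11, MMAA at 0.63 ± 0.24 and ABCD4 at 0.22 ± 0.11, and none of the 14 tested passed edgeR over all genes or over the list alone.

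The keratinocyte differentiation list lay higher. Of 27 tested members 20 were positive and 7 negative, 5 rose over all genes and 10 adjusted over the list alone, with a median of 0.29 and a camera adjusted p of 7.4e-06, or 0.419 with an estimated correlation. The suprabasal keratins KRT10 and KRT1 rose from 135.8 ± 2.36 to 244.6 ± 0.79 and from 225.9 ± 4.47 to 385.3 ± 12.7 FPKM, log2 fold changes of 0.84 ± 0.08 and 0.77 ± 0.08 with edgeR adjusted p of 0.0038 and 0.0071. The mucosal keratin KRT4 rose by 0.52 ± 0.08 and the cornified envelope precursor SPRR1B by 0.80 ± 0.13. The remaining member that rose, named outside the rule, was the mucosal keratin KRT13, at 0.55 ± 0.09 with 16.3% of its exonic bases under another gene. Members on the other side, chosen after their values were seen, included the late markers FLG at -0.02 ± 0.13, FLG2 at -0.24 ± 0.25 and LORICRIN at -0.48 ± 0.50, the envelope protein PPL at -0.06 ± 0.11 and the transcription factor GRHL3 at -0.31 ± 0.12, none of which passed. The basal keratinocyte list did not pass, with a camera adjusted p of 0.128 and 0 of 18 members called over all genes. KRT15, a basal keratin, stood at 0.50 ± 0.09 and passed adjusted over the list alone, as 1 member did, while DST and COL17A1 stood at 0.27 ± 0.09 and 0.20 ± 0.10. The share of mitochondrially encoded counts was higher in the same libraries as the differentiation list.

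**Figure D3:**
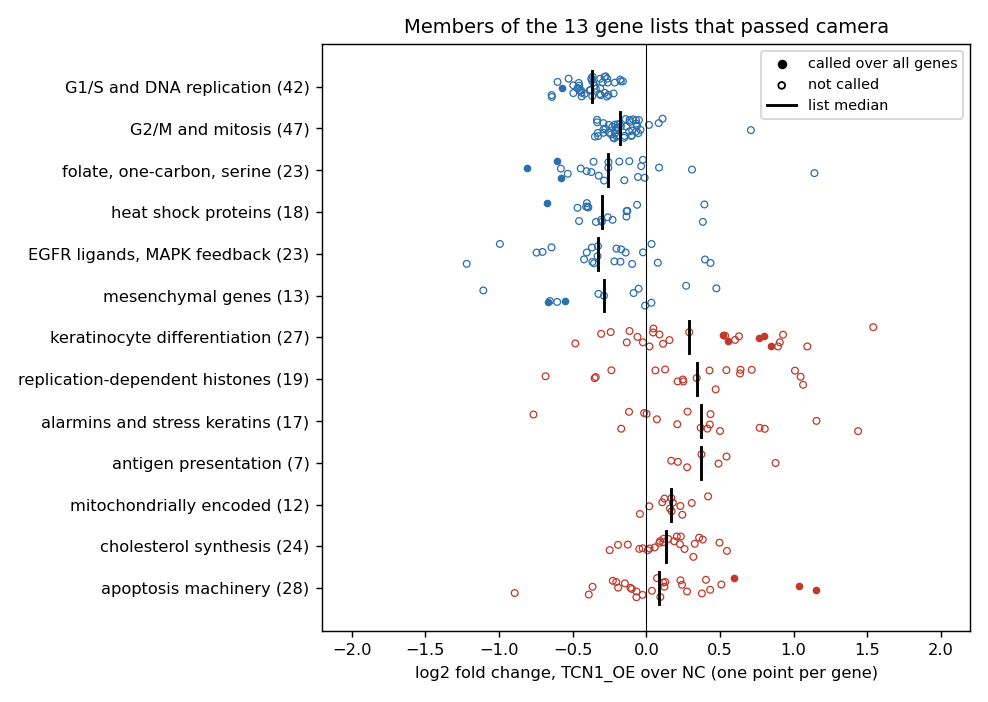
Log2 fold change of TCN1_OE over NC (horizontal axis) for each tested member of the 13 gene lists that passed camera, with the number of members tested in brackets; lists lower in TCN1_OE are blue, lists higher are red, filled points passed edgeR over all genes and black bars are list medians. All 42 G1/S members lie left of 0 around a median of -0.37, while the 27 differentiation members spread on both sides of 0 around a median of 0.29.

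The list of alarmins and stress keratins also lay higher, with 13 of 17 tested members positive, a median of 0.37 and a camera adjusted p of 1.0e-04, or 0.357 with an estimated correlation. None passed over all genes and 9 rose adjusted over the list alone. The calprotectin genes S100A8 and S100A9 stood at 0.77 ± 0.17 and 0.80 ± 0.18, psoriasin S100A7 at 1.15 ± 0.30, from 3.97 ± 1.09 to 9.07 ± 1.39 FPKM, and the serpin SERPINB4 at 0.41 ± 0.10. The stress keratins, named outside the rule, went both ways: KRT6A, KRT6B and KRT17 stood at -0.12 ± 0.12, -0.77 ± 0.49 and -0.17 ± 0.11, and KRT16 at 0.44 ± 0.15. The antigen presentation list was higher on 7 tested members, all positive, with a median of 0.37, or 0.29 over the 6 that camera used, a camera adjusted p of 0.0011 and 0.395 with an estimated correlation. None passed edgeR over all genes or over the list alone, and HLA-B, PSMB10, B2M and CD74 stood at 0.37 ± 0.12, 0.49 ± 0.16, 0.21 ± 0.09 and 0.54 ± 0.23. This list rests on few genes, because 2 of 180 protein-coding genes of the major histocompatibility complex reached 1 FPKM, and 18.9% of the exonic bases of HLA-B and 34.8% of those of PSMB10 lie under another gene. Without a filter on low values the list was not called, with an adjusted p of 0.0683.

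Heat shock proteins lay lower, with 16 of 18 tested members negative, a median of -0.30 and a camera adjusted p of 2.5e-05, or 0.421 with an estimated correlation. HSPA8 fell over all genes, and adjusted over the list alone 10 fell and 1, HSPB1 at 0.38 ± 0.12, rose. HSPH1, HSPD1 and STIP1, a chaperone, a mitochondrial chaperonin and a co-chaperone, stood at -0.47 ± 0.09, -0.46 ± 0.08 and -0.40 ± 0.08. The list of EGFR ligands and MAPK feedback genes was lower as well, with 19 of 23 tested members negative, a median of -0.33, or -0.23 over the 20 that camera used, and a camera adjusted p of 1.0e-04, or 0.357 with an estimated correlation. None passed over all genes and 7 fell adjusted over the list alone. The AP-1 subunit FOSL1 stood at -0.99 ± 0.19, from 10.5 ± 0.73 to 5.30 ± 1.08 FPKM, the MAPK phosphatase DUSP4 at -0.70 ± 0.14, PHLDA1 at -0.40 ± 0.11 and the transcription factor ETV5 at -1.22 ± 0.33. ETV5 had a mean under 1 FPKM and was likewise not used by camera.

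The list of mesenchymal genes was lower, with 10 of 13 tested members negative, a median of -0.29 and a camera adjusted p of 0.0151, or 0.397 with an estimated correlation; the 10 members that camera used had a median of -0.16. THBS1 and fibronectin FN1 fell over all genes, and 4 fell adjusted over the list alone; FN1 went from 12.7 ± 0.63 to 8.69 ± 0.34 FPKM. N-cadherin CDH2 and tenascin TNC stood at -1.11 ± 0.23 and -0.61 ± 0.13. CDH2 had a mean under 1 FPKM, so camera did not use it. The apoptosis list was higher with a camera adjusted p of 0.0414, or 0.428 with an estimated correlation, although its members went both ways, 16 of 28 positive with a median of 0.08. BMF, CASP14 and the death ligand TNFSF10 rose over all genes, and adjusted over the list alone 4 rose, the other being the caspase-8 inhibitor CFLAR, and 1, BID at -0.39 ± 0.11, fell; CASP14 is known for cornification rather than apoptosis. TNFSF10 went from 48.8 ± 2.90 to 74.0 ± 9.87 FPKM, and CFLAR stood at 0.51 ± 0.12. Cholesterol synthesis genes were higher with a camera adjusted p of 0.0094, or 0.395 with an estimated correlation, on 19 of 24 positive members and a median of 0.13. None passed over all genes and 1, the sterol carrier STARD4 at 0.50 ± 0.11, rose adjusted over the list alone, while INSIG1 and SC5D stood at 0.36 ± 0.10 and 0.32 ± 0.10. The mesenchymal list lost its call without NC replicate 2 (adjusted p 0.0507) and without TCN1_OE replicate 1 (0.0797), and the apoptosis list without the same libraries (0.115 and 0.203), while the cholesterol list lost it without NC replicate 1 (0.135) and without TCN1_OE replicate 2 (0.112). Filters changed 2 of these calls, with a camera adjusted p of 0.163 for the mesenchymal list from 5 FPKM. For the apoptosis list the camera adjusted p was 0.0520 from 5 FPKM, 0.200 from 0.1 FPKM and 0.329 without a filter. On log2 CPM of the genes tested by edgeR, which changes the measure as well, the apoptosis list had 0.221.

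The other 18 lists did not pass, with camera adjusted p from 0.116 to 0.993. They were fatty acid and lipid synthesis, immediate early genes, basal keratinocyte genes, JAK-STAT feedback, the ER stress response, cytosolic ribosomal proteins, hypoxia, matrix proteases, nuclear OXPHOS genes, cytokines and chemokines, glycolysis, NRF2 targets, p53 targets, sweat and sebaceous gland markers, NF-kB targets, cobalamin handling, interferon-stimulated genes, and Notch, Wnt and TGF-beta targets. Single members of these lists passed all the same. The p53 targets TP53INP1 and BTG2 rose, BTG2 from 32.2 ± 1.66 to 47.9 ± 1.06 FPKM. AEN and CDKN1A stood at -0.81 ± 0.17 and 0.39 ± 0.11 without passing over all genes. Adjusted over the list alone 3 members rose, CDKN1A among them, and 1, AEN, fell. The list had a camera adjusted p of 0.657. DDIT4, a stress-induced inhibitor of mTORC1 in the hypoxia list, rose from 143.6 ± 6.77 to 219.2 ± 19.8 FPKM with 41.2% of its exonic bases under another gene, and NDRG1 and MXI1 stood at 0.37 ± 0.10 and 0.42 ± 0.14. For 8 of these 18 lists the median, the mean and the test differed in sign, among them cobalamin handling, p53 targets, nuclear OXPHOS genes and interferon-stimulated genes, and for the 13 lists that passed they did not. Markers of fibroblasts, melanocytes, immune cells and endothelium were too low for camera. Of these, 3, 3, 2 and 2 genes were tested by edgeR and none was called over all genes; adjusted over the list alone 1 fell, the fibroblast marker MFAP5 at -1.41 ± 0.34, from 0.836 ± 0.072 to 0.314 ± 0.049 FPKM.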

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

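The alternatives without robust estimation, with median-of-ratios factors, with thinned counts and with camera on log2 CPM were chosen after seeing the data. The TCN1 rise stayed called in all 22 alternatives. No reversal of direction was recorded for the genes followed one by one or for the 13 lists that passed. Reversals were not looked for in lists that had not passed, nor where a gene had no adjusted p, as DHRS4 and H2AC8 in 1 alternative each. The number of genes called did not hold. Limma on log2 FPKM, with any of the 3 pseudocounts, 3 further scalings or no trend, called 1 gene higher and 0 lower. In the simulation limma recovered 14 of 67 genes changed by 1.5-fold, 52 of 67 by 2-fold and 63 of 66 by 4-fold. EdgeR recovered 46, 64 and 66 of them. The simulated counts were drawn with the spread that edgeR had fitted, so these numbers do not account for the calls lost with limma. Filters on edgeR's genes gave 139 higher and 138 lower from 0.1 FPKM, 200 and 275 with none, 31 and 14 from 1 FPKM, and 12 and 2 from 5 FPKM. Library totals without TMM gave 69 and 63, DESeq2 95 and 109, and a 2-fold minimum 16 and 5 by construction. Leaving out 1 library gave 104 to 188 higher and 106 to 142 lower genes, with 70 to 74 of the 75 called genes shared; the lone library of a group is then assumed to vary like the other group. The cause of these shifts was not tested. Of 51 called genes besides TCN1 that were followed one by one, limma called 0 (44 lost their call and 7 were not tested); edgeR from 1 FPKM lost 13 and left 7 untested, and from 5 FPKM lost 30 and left 10 untested. For the lists, an estimated correlation left 0 and fry 3 (G1/S, folate and EGFR feedback) of 13, and the other 16 alternatives left 11 to 15. With the replicate number as a block, edgeR called 1216 higher and 1655 lower genes, all 75 among them, and 12 lists passed, without the apoptosis list (adjusted p 0.0798); differences between replicates 1 and 2 correlated across 8099 genes between the groups (r = 0.64), but 2 pairs and labels that give no shared day do not make it a paired design. Depth limits genes near the floor of 3 counts.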

Other observations

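The tests of ribosome assembly and FOXO target genes, of the major histocompatibility complex (MHC), of neighbouring genes, and of length, GC content and depth in the differentiation list were chosen only after the results were seen; those of overlapping genes, of culture density, and of length, GC content and depth in the G1/S list were written down before their results.

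Among the called genes, 9 take part in nucleolar ribosome assembly, outside the fixed lists, and all 9 fell: NOLC1 (from 61.6 ± 3.56 to 41.4 ± 0.66 FPKM), URB2, TSR1, TCOF1, DDX21, DKC1, POLR1B, NOP56 and WDR43. A list of 74 such genes was drawn up after this was seen, when all fold changes were available, so its values depend on the choice of members. Of its 70 tested members 67 were negative, and the 61 that were not called had a median of -0.34 on the log2 scale, 58 of them negative, with a camera (limma) p of 2.7e-17, or 0.0334 with an estimated correlation. These p-values are not adjusted for the number of lists; the G1/S list, unadjusted and with an estimated correlation, has 0.0103. A lower ribosome assembly programme in the TCN1_OE libraries is a hypothesis consistent with these values. With edgeR from 1 FPKM, TSR1, TCOF1, DDX21, DKC1, POLR1B, NOP56 and WDR43 were no longer called, with adjusted p from 0.0538 to 0.0567. Without NC replicate 1, DDX21, DKC1 and NOP56 were not called (edgeR adjusted p 0.0614, 0.0667 and 0.0768), nor was DDX21 without TCN1_OE replicate 2 (0.0570), and 20.8% of the exonic bases of TSR1 lie under another gene.

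Likewise 3 called genes that were taken here as FOXO targets rose: TXNIP (from 42.0 ± 1.68 to 76.6 ± 2.27 FPKM), PIK3IP1 and TP53INP1. Other called genes may be FOXO targets too. In a list of 28 such genes drawn up after this was seen, 26 were positive, and the 25 not called had a median of 0.23, 23 of them positive, with a camera p of 9.0e-06, or 0.0394 with an estimated correlation, likewise unadjusted. The members were chosen when all fold changes were available and are not a complete set of FOXO targets. These counts and p-values therefore depend on that choice. Higher FOXO activity is a hypothesis only, since no protein was measured here.

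Some genes that most cells express were listed near 0. Of 149 ribosomal protein, OXPHOS and glycolysis genes, 22 had a mean under 1 FPKM, among them COX5B (0.0208), LDHA (0.0972), SDHB (0.136) and RPS18 (0.214). Loss of reads shared with overlapping genes is argued against as the whole cause, since 2 of the 22 (9.09%) had 50% or more of their exonic bases under another gene and 8 had under 10%; as a part of it, it stays open, since the shares among the 127 other genes were 0.787% and 95 of 127. In the MHC, which has alternate copies in GRCh38, 1.11% of 180 protein-coding genes reached 1 FPKM, against 50% of 864 on the rest of chromosome 6 (Fisher's exact p 6.63e-44), so reads with more than one place to align may have been left out of the counts. The alignments were not used here, so this stays a hypothesis, and no biological explanation was tested.

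The large folds of called genes besides TCN1 lay more often beside genes listed near 0. For 11 called genes with a log2 fold change of 1.2 or more in size, among them NOMO1 (-3.54), DHRS4 (counts of 66, 13, 1 and 1, and, without NC replicate 1, a log2 fold change of -3.97 that was not called, with an edgeR adjusted p of 0.164), PIP4P1 (2, 7, 143 and 62), MOB2 (7, 4, 142 and 32), FLII, LY6E and PLA2G2A, 78.4% of the neighbouring genes on average were under 1 FPKM, against 45.8% for 61 other called genes (permutation p 0.00232). Single values varied, with 36.4% for BCO2, 50% for FAN1 and 60% for FLII, and TCN1 itself had 72.7%. In genes of matched expression the mean was 46.0%, with a range of 30.8 to 61.8% over 95% of the draws. The measure cannot separate neighbours that lost reads from neighbours silent in these cells, and loss was not compared between libraries. Uneven loss of reads between libraries is a candidate explanation for these folds that was not tested, and a change in the cells stays open.

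Lower replication genes together with higher differentiation genes may reflect TCN1 or another difference between the cultures. For the replication genes a trend with length and GC content is argued against. The G1/S median was -0.37 before and -0.37 after its removal (95% bootstrap interval over the list's genes -0.41 to -0.33). Thinning to the smallest library also left it at -0.37 (-0.42 to -0.30). Thinning keeps each gene's expected share of the counts, so it could hardly move this median and does not decide on unequal depth. The largest and the smallest library totals were both in NC. The bootstrap intervals in this paragraph resample the genes of a list as if independent. They hold no spread between libraries. In the differentiation list removal of the trend and thinning moved the members by a median of -0.02 (-0.04 to -0.01) and 0.001 (-0.01 to 0.01), against a median of 0.29. The camera adjusted p after them was 2.9e-05 and 1.5e-05, where an estimated correlation had given 0.419 without them. The list's own median after removal of the trend had a wide interval (0.25, from 0.0029 to 0.63). Dense keratinocyte cultures also slow down and differentiate, and YAP/TAZ targets, which fall with density, had a camera p of 0.105 and a median of -0.06 (-0.20 to 0.01). Density and TCN1 cannot be told apart here, because each group is a single transduced line and no label gives its density. A shortage of cobalamin through its binding by TCN1 was not tested.

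In 33 genes 1 library held at least 50 counts and, scaled to library totals, more than 4 times the next library. The highest was NC replicate 1 in 10, NC replicate 2 in 12, TCN1_OE replicate 1 in 6 and TCN1_OE replicate 2 in 5. In that order of libraries, the counts were 1500, 11, 21 and 25 for CANX, 42, 575, 44 and 37 for APEX1, and 38, 35, 31 and 726 for PSME1.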
